A study of Homo sapiens with 4 samples.

How the data were processed

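RNA sequencing counts from KELLY cells with lentiviral WT or M3 IWS1-FLAG were analysed. Per the labels, cells were kept in medium with 10% fetal bovine serum, selected with 1 ug/ml puromycin and harvested at 50% confluency, and libraries were made from poly(A) RNA in fragments of 200 to 400 bp. The deposited values are whole read counts per gene symbol, 1 table per library with 28063 genes, and the authors did not normalise them. Per the submitters' processing notes, HISAT2 2.1.0, HTSeq, DESeq2 and the hg38 build were used. The annotation and the strand setting used for counting are not given in the sources used here, so reads of overlapping sense and antisense genes cannot be told apart. Each table ends in 5 summary values, of which 3 are 0 in every library. Reads assigned to no annotated feature made up 23.3%, 23.2%, 27.5% and 25.6% of all counted reads in WT 1, WT 2, M3 1 and M3 2. Reads that overlapped several genes made up 3.50%, 3.41%, 3.16% and 3.34% in the same order. These summary values were kept out of library sizes and tests. Gene count totals ran from 12289685 in M3 1 to 20962372 in WT 2.

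Groups and replicate numbers came from the sample labels. M3 was compared with WT in 1 model without covariates, with edgeR 4.0.16 under R 4.3.3: filterByExpr, TMM factors (0.916 and 1.01 in WT, 1.05 and 1.04 in M3), a robust quasi-likelihood fit and F test, and Benjamini-Hochberg adjustment with a threshold of 0.05. The standard error of a log2 fold change is its size divided by the root of the F statistic. The biological coefficient of variation was 0.124. An exact permutation test of 2 against 2 libraries cannot go below p = 0.333, so no such test is given. Per-library CPM are TMM-normalised. The tests of intronic microRNA genes, of gene families not known to be in use and of downstream genes used total gene counts instead.

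The 33 gene lists, the test, the alternatives and the rule for named genes were fixed before the data were examined. The rule names IWS1, the 12 genes with the largest rise and the 12 with the largest fall among changed genes with a mean of at least 5 CPM, non-overlapping groups and a gene symbol that is not a bare identifier, and up to 4 changed members per list by size of change, or up to 2 unchanged members of highest CPM. Where a list's count was 5 or fewer, its other members were named too, after their values were seen, as were MYCN, KLF7, ID1, ID2, FZD7, SMAD6, SMAD7 and BAMBI. A few genes that would be named in this way are not reported here. Lists with at least 5 tested members (30 of 33) were tested with camera of limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01, and again with an estimated correlation and with fry. Of the 5 lists that passed, none passed with an estimated correlation or fry. With an estimated correlation camera takes its degrees of freedom from the few libraries, so a set can fail there even at a low correlation. For genes of chromosome 16 the estimated correlation was 0.0104, near the preset 0.01, yet the unadjusted camera p went from 0.000912 to 0.0824. Such a failure therefore does not show that correlation between genes explains a call. Members of the mitochondrially encoded list were not found under the symbols fixed for them, so that list was not analysed here. The median, mean and test direction differ in sign for Pol II elongation factors (-0.11, 0.08, up), Schwann and glial markers (0.09, -0.03, up), G2/M genes (-0.00055, 0.10, up), hypoxia genes (0.02, 0.02, down), cholesterol genes (0.01, -0.07, down), chaperones (-0.05, 0.01, down) and splicing factors (-0.02, 0.04, down).

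Gene positions came from a RefSeq table of GRCh38.p14, of the same build family as hg38, and transcript length, GC content and exon overlaps from GENCODE release 29. Of the 28063 symbols, 26073 matched RefSeq by symbol and 1012 by a synonym, and 978 did not match. The counts of UBR7, CCDC144B, CHCHD10, ZNF460, CCDC39, CSNK1E, RN7SK, OST4, KMT2A, PRPH, NME1, HSPE1, RPS10, RPL38, UQCRQ, NDUFA1, CCNE2, TYMS, CEBPB, DDIT4, ALDOC, FDPS, SNHG6, SNHG8, HOXC4 and CD68 are uncertain because over 10% of their exonic bases lie in another annotated gene. Positions were found for 98.2% and a transcript for 96.9% of tested genes. The tests of genomic span compared the 1389 genes of longest and the 1389 of shortest span with the rest.

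The alternatives were other scaling (median-of-ratios, upper quartile), no or a stricter count filter (a mean of 50), the replicate number as a block, each library left out, DESeq2 1.42.0, limma-voom, a 2-fold threshold and an adjusted p of 0.01. Added after seeing the data were a correction for transcript length and GC content (splines with 5 degrees of freedom per library, entered as offsets, on 13702 genes with a transcript), the same with the block, the uncorrected fit on those genes, total-count scaling and crossed pairing. With a library left out, 1 group has a single sample, which is assumed to vary like the other group. Calls gained without a WT library or lost without an M3 library therefore rest on the spread of the other pair. That spread was smaller between the M3 libraries than between the WT libraries. Counts without a length or GC trend were simulated for the 14141 genes of this comparison. There the edgeR fit recovered 19.4% of genes changed 1.5-fold, 71.6% changed 2-fold and 93.9% changed 4-fold, with 5 false calls among 128. In a second simulation, on 13702 genes, a transcript length and GC trend was added to M3. The correction then lowered the rho of fold change with transcript length from 0.74 to 0.05. The uncorrected fit called 5435 genes that only the trend had shifted, against 7 with the correction. It called 77.4% of the genes with a simulated change, against 62.1% with the correction, counted in either direction. Calls that the trend alone would give are among the 77.4%, so these shares do not compare the power of the 2 fits. Python 3.11.15, scipy 1.17.1 and matplotlib 3.10.9 were used for the remaining tests and plots.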

Results

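Poly(A) RNA was measured in KELLY cells, a human neuroblastoma line with amplified MYCN. The cells had been transduced with lentivirus for FLAG-tagged IWS1, a factor that takes part in transcription elongation by RNA polymerase II. One group expressed the wild-type (WT) protein and the other a mutant form (M3) in which a TIM was disrupted. A TIM is a short disordered motif through which such factors bind the TFIIS N-terminal domain (TND) of partner proteins. Each group had 2 libraries. The read counts assigned to genes were 13645171 and 20962372 in WT libraries 1 and 2 and 12289685 and 13581628 in M3 libraries 1 and 2. Reads assigned to no annotated feature made up 23.3% and 23.2% of all counted reads in WT and 27.5% and 25.6% in M3. The labels do not say that the libraries came from separate cultures, so the p-values measure only the spread between these libraries, which may be technical. The libraries of a group differed by more than sampling noise, with a chi-square per degree of freedom of 23.9 for the WT pair and 4.66 for the M3 pair, beside 25.1 for WT library 2 against M3 library 2 and 34.4 to 77.6 for the other pairs across groups, and none was treated as a repeat of another.

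The single comparison asked how RNA levels differed between cells with M3 and with WT IWS1. IWS1 itself (chromosome 2, 127480812 to 127527336, GRCh38) was counted at 382 ± 16.6 CPM (counts per 1e6 gene counts; SD, n = 2) in WT and 598 ± 1.93 in M3, from 4624 and 8289 reads in WT libraries 1 and 2 and 7654 and 8443 in M3. It was 1.56-fold higher in M3, a log2 fold change of 0.65 ± 0.12 (SE; edgeR quasi-likelihood adjusted p = 0.0225), and both M3 libraries lay above both WT libraries. Reads of the vector-borne and the endogenous gene are counted together if the vector keeps the coding sequence, which was not checked. This value therefore does not check which form the cells carried. With M3 library 1 left out the log2 fold change was 0.65 with an adjusted p of 0.203, and with M3 library 2 left out it was 0.64 with an adjusted p of 0.134.

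Of 14141 genes tested, 2232 (15.8%) differed between M3 and WT, 1295 higher and 937 lower in M3. The change was at least 2-fold for 249 of the higher and 104 of the lower genes, and the median log2 fold change was 0.75 among the higher and -0.67 among the lower genes. UBR7, a member of the UBR-box family of ubiquitin ligases, had the largest rise among genes eligible to be named (log2 fold change 2.47 ± 0.28), from 1.68 and 1.43 CPM in WT to 7.56 and 9.51 in M3. GPRIN3, a G protein-regulated inducer of neurite outgrowth family member, rose by 2.02 ± 0.30, and CHCHD10, a mitochondrial intermembrane space protein, by 1.78 ± 0.37. The zinc finger gene ZNF460 (1.77 ± 0.29), the monocarboxylate transporter SLC16A7 (1.73 ± 0.31), the laminin chain LAMA3 (1.69 ± 0.23), the corticotropin-releasing hormone gene CRH (1.69 ± 0.43), NHLRC2 (1.63 ± 0.22) and PWAR5, a noncoding RNA of the Prader-Willi region (1.70 ± 0.21), were also higher. CCDC144B (1.84 ± 0.33), ANKRD36C (1.61 ± 0.35) and CCDC39 (1.59 ± 0.31) completed the 12, with uncertain counts because the first 2 have near-identical copies and 26.9% of the exonic bases of CCDC39 lie in other genes. CHCHD10 and CRH lost the call with either WT library left out (adjusted p from 0.0963 to 0.514). CHCHD10 (1.08), ANKRD36C (1.28) and CCDC39 (1.12) lost it without M3 library 1 (0.0585, 0.0655 and 0.101), and CRH lost it without M3 library 2, where its log2 fold change was 0.74 (0.246). With each library's trend on transcript length and GC content removed SLC16A7 (0.70, adjusted p = 0.0868), CCDC144B (1.18, 0.0509) and CRH (1.94, 0.0777) lost the call, and CRH also with total-count scaling (0.0517) and limma-voom (0.0632).

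**Figure D1:**
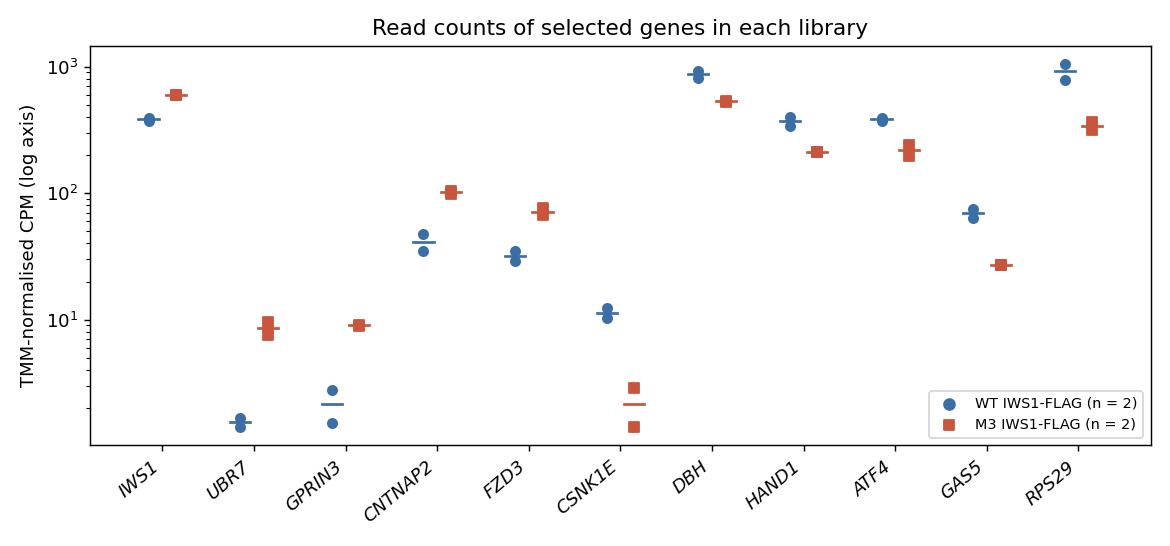
TMM-normalised CPM, on a log axis, of 11 genes in the 2 WT (circles) and 2 M3 (squares) libraries, with a line at each group mean. UBR7, the gene named with the largest rise, stands at 1.68 and 1.43 CPM in WT and 7.56 and 9.51 in M3.

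The largest fall was that of CSNK1E, which encodes casein kinase 1 epsilon, with a log2 fold change of -2.41 ± 0.31, from 10.3 and 12.4 CPM in WT to 2.88 and 1.42 in M3. In this gene 21.1% of exonic bases are shared with a read-through gene on the same strand, so its count is uncertain. LSM14A, a component of cytoplasmic mRNP granules, fell by 1.69 ± 0.32, AKR1C3, an aldo-keto reductase, by 1.58 ± 0.23 and CALY, a neuronal vesicle protein, by 1.42 ± 0.28. The ubiquitin-ribosomal fusion gene RPS27A (-1.50 ± 0.13), RPS29 (-1.44 ± 0.17), the snoRNA host genes SNHG19 (-1.77 ± 0.20) and GAS5 (-1.36 ± 0.14) and the oligosaccharyltransferase subunit OST4 (-1.40 ± 0.16) were lower, as were the pseudogene RPL21P28 (-2.01 ± 0.29) and the mitochondrial 12S rRNA RNR1 (-1.38 ± 0.20). RN7SK, the 7SK RNA that holds P-TEFb inactive, had a lower count by the same test (-1.76 ± 0.42). It had 73 and 310 reads in WT libraries 1 and 2 and 32 and 52 in M3, with most reads in WT library 2. The libraries were made from poly(A) RNA, so this count need not follow the level of 7SK RNA in the cells. AKR1C3, RPL21P28, RN7SK and the ribosomal protein genes have close paralogs or pseudogenes that can share reads. RNR1 lost the call without M3 library 1 (adjusted p = 0.0767). RN7SK lost it with the length and GC trends removed (-1.40, adjusted p = 0.182), with total-count scaling (0.0652) and with limma-voom (0.0527). Without WT library 2 the log2 fold changes of RN7SK and LSM14A were -0.91 and -1.07, both past the threshold.

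These counts came from edgeR's quasi-likelihood test at a Benjamini-Hochberg adjusted p below 0.05. The smallest adjusted p was 0.0185, and 5078 genes had an unadjusted p below 0.05. The groups did not overlap in 68.2% of tested genes, where chance gives 33.3% for a single gene. Genes are not independent, and a trend shared by many genes can raise this share. The contrast therefore does not tell a group effect from a trend between libraries. The count of changed genes was 3571 without WT library 1, 6770 without WT library 2, 366 without M3 library 1 and 1079 without M3 library 2. It was 661 (286 higher, 375 lower) once each library's trend on transcript length and GC content was removed, and 445 of these were called in the same direction before. With total-count scaling the split was 856 higher (76.4%) and 264 lower, beside 58.0% higher with TMM scaling, and the median log2 fold change of all genes was 0.12 higher than with TMM, so directions here are relative to the TMM centre.

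Cytosolic ribosomal protein genes were lower in M3 as a group: 51 of the 62 measured fell, none rose, and the list median was -0.77 (camera adjusted p = 2.27e-18 with the preset correlation, 0.807 with an estimated correlation). Adjusted over the list alone, 60 fell. RPS29, RPS10 (-1.42 ± 0.27), RPL38 (-1.14 ± 0.19) and RPL11 (-1.08 ± 0.19) moved most, and 39.4% of the exonic bases of RPS10 are shared with a read-through gene. Of 20 snoRNA host genes, whose introns carry small nucleolar RNAs, 11 fell and none rose (16 and 0 adjusted over the list alone), with a median of -0.70 (camera adjusted p = 5.34e-07, and 0.807 with an estimated correlation). SNHG6 (-1.21 ± 0.15) and SNHG8 (-1.04 ± 0.20) followed SNHG19 and GAS5. Among 49 nuclear genes of oxidative phosphorylation 13 fell and 1 rose (27 and 1 adjusted over the list alone), with a median of -0.43 (camera adjusted p = 2.49e-07, and 0.807 with an estimated correlation). UQCRQ of complex III (-0.99 ± 0.19) and NDUFA1 (-0.79 ± 0.17) and NDUFB10 (-0.73 ± 0.19) of complex I fell, as did COX4I1 of complex IV (-0.67 ± 0.18), and NDUFA5 rose by 0.49. Transcripts of these lists are short, with median lengths of 844, 1105 and 1098 nt against 3052 nt for tested genes. With the length and GC trends removed the medians were -0.48, -0.54 and -0.24 with camera adjusted p = 2.33e-17, 3.15e-06 and 8.47e-06 at the preset correlation, and no call with an estimated correlation (adjusted p = 0.943, 0.933 and 0.943). Without WT library 1 the oxidative phosphorylation median was -0.25, with a call (camera adjusted p = 8.51e-05, and 0.936 with an estimated correlation). Of the 12 genes named from these lists, RPL38, RPL11, NDUFA1, NDUFB10, COX4I1 and SNHG8 lost the call without M3 library 1 (adjusted p from 0.0930 to 0.282), and NDUFB10 and COX4I1 also without M3 library 2 (0.0531 and 0.0863). With the trends removed NDUFA1 (-0.40), NDUFB10 (-0.23) and COX4I1 (-0.27) lost it (adjusted p = 0.0613, 0.258 and 0.168), as NDUFB10 and COX4I1 did with total-count scaling (0.0654 and 0.0586). NDUFB10 was at -0.40 and COX4I1 at -0.39 without WT library 1.

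**Figure D2:**
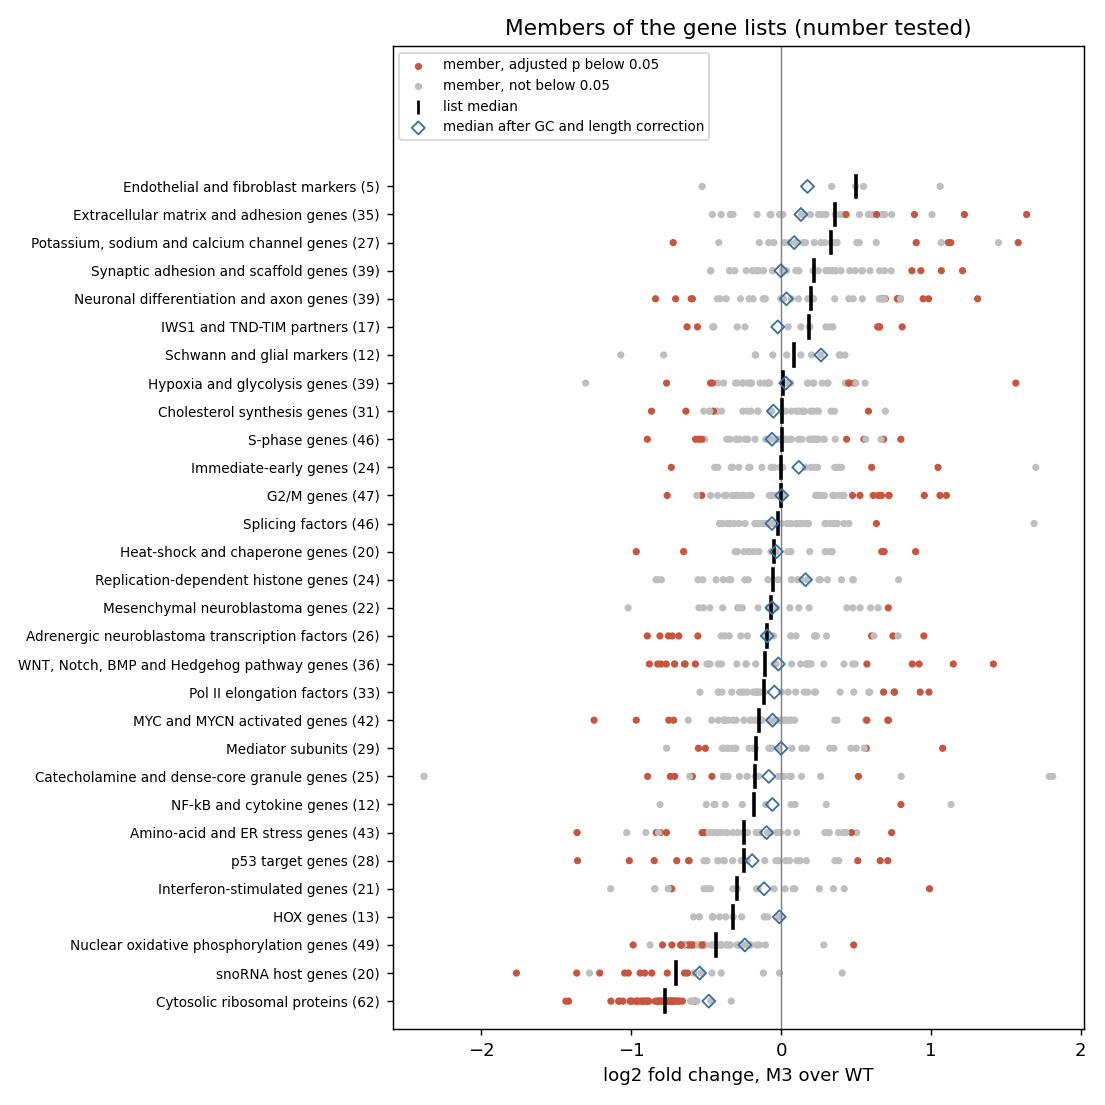
Log2 fold change (M3 over WT) of each tested member of 30 gene lists, with the list median as a bar and the median after removal of the length and GC trends as a diamond; red points passed an adjusted p of 0.05 over all genes. The ribosomal protein list has the lowest median, -0.77, which is -0.48 after the correction.

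Genes for ion channels and for the extracellular matrix were higher in M3 as lists in the reported fit, though not under every count filter. Of 27 potassium, sodium and calcium channel genes 4 rose and 1 fell (4 and 2 adjusted over the list alone), with a median of 0.33 (camera adjusted p = 0.0244, and 0.807 with an estimated correlation). They were KCNJ6, an inward rectifier (1.58 ± 0.43), the calcium channel subunit CACNA2D1 (1.13 ± 0.19), the sodium channels SCN3A (1.12 ± 0.25) and SCN9A (0.90 ± 0.25), and KCNH6, which was lower (-0.72). Of 35 matrix and adhesion genes 5 rose and none fell (6 and 0 adjusted over the list alone), with a median of 0.36 (camera adjusted p = 0.0163, and 0.807 with an estimated correlation). They were thrombospondin 2 (THBS2, 1.64 ± 0.31), integrin alpha V (ITGAV, 1.22 ± 0.23), versican (VCAN, 0.89 ± 0.21), integrin alpha 6 (ITGA6, 0.64 ± 0.17) and N-cadherin (CDH2, 0.43). Transcripts of both lists are long, with medians of 6194 and 5811 nt. With the trends removed the channel list had a median of 0.09 and no call (camera adjusted p = 0.159). None of its members passed there (0 higher, 0 lower). The matrix list had a median of 0.13, with 2 members higher and 0 lower. Its call (camera adjusted p = 0.0297) ended with an estimated correlation (0.933). Without a count filter neither list passed (adjusted p = 0.0686 for each), and with the stricter filter the channel list did not pass (0.0948). Without WT library 1 the channel list had a median of 0.13 and no call (adjusted p = 0.0872), and the matrix list a median of 0.23 with a call (0.0442, and 0.936 with an estimated correlation).

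Neuronal genes went in both directions. Of 39 differentiation and axon genes 8 rose and 4 fell (11 and 5 adjusted over the list alone; camera adjusted p = 0.242). The neurexin family gene CNTNAP2 (1.31 ± 0.16), the guidance cue SEMA3A (0.99 ± 0.16) and the microtubule protein MAP2 (0.95 ± 0.17) rose, while peripherin (PRPH, -0.84 ± 0.17), the microtubule protein MAPT (-0.70) and STMN4 (-0.59) fell. PRPH shares 56.2% of its exonic bases with an antisense gene. Of 39 synaptic adhesion and scaffold genes 4 rose and none fell (2 and 0 adjusted over the list alone; camera adjusted p = 0.2): SYN3 (1.21 ± 0.35), NLGN1 (1.07 ± 0.25), HOMER1 (0.93 ± 0.21) and RIMS2 (0.87 ± 0.23). The synaptic list passed without WT library 2 (camera adjusted p = 0.0209, and 0.876 with an estimated correlation) and without M3 library 2 (0.0275, and 0.863 with an estimated correlation). Of the 16 genes named by the rule from these 4 lists, 10 lost the call without M3 library 1 and SCN9A also without M3 library 2 (adjusted p = 0.0558), 9 lost it with the trends removed and 6 with total-count scaling, and SYN3 lost it with upper-quartile scaling (0.0542) and KCNJ6 with DESeq2, which gave it no adjusted p. The log2 fold change of SYN3 was 0.80 without WT library 1 and 1.96 without WT library 2.

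Transcription factors of the adrenergic state, which defines most neuroblastoma lines, moved apart. Of 26 measured, 3 rose and 6 fell (5 and 9 adjusted over the list alone; camera adjusted p = 0.479). HAND1 (-0.81 ± 0.13) and TBX2 (-0.75 ± 0.11) fell, and DACH1 (0.95 ± 0.20), KLF7 (0.75) and EYA1 (0.60) rose. MYCN was at 2386 and 2385 CPM in WT and 2247 and 2258 in M3 (log2 fold change -0.08 ± 0.16, adjusted p = 0.736). Of 25 catecholamine and dense-core granule genes 5 fell and 1 rose (6 and 2 adjusted over the list alone; camera adjusted p = 0.346). Dopamine beta-hydroxylase (DBH, -0.71 ± 0.14) and tyrosine hydroxylase (TH, -0.59 ± 0.13), enzymes of noradrenaline synthesis, the neuropeptides NPY (-0.89 ± 0.26) and galanin (GAL, -0.74 ± 0.15) and synaptophysin (SYP, -0.46) were lower, and GCH1 (0.52) was higher. Among 22 mesenchymal-state genes COL5A1 rose (0.72 ± 0.18; none adjusted over the list alone; camera adjusted p = 0.999), and among 13 HOX genes HOXC4 fell (-0.46 ± 0.13; none adjusted over the list alone; camera adjusted p = 0.0729, 0.0404 without M3 library 2 and 0.00337 without a count filter, where an estimated correlation gave 0.863 and 0.844). All 9 genes named here by the rule from these 4 lists lost the call without M3 library 1 and 6 of them without M3 library 2, while NPY also lost it without WT library 1 (adjusted p = 0.0542), with DESeq2 (0.109), with limma-voom (0.0551) and with total-count scaling (0.0867). HOXC4 lost it with DESeq2 (0.0514), total-count scaling (0.130) and the replicate block (0.103). With the trends removed HAND1 (-0.48), TBX2 (-0.52), DBH (-0.56) and DACH1 (0.66) stayed past the threshold and TH (-0.21), GAL (-0.24), NPY (-0.50), COL5A1 (0.57, adjusted p = 0.0922) and HOXC4 (-0.28, 0.137) did not.

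Markers of other cell types gave no list call. None of 12 Schwann and glial markers passed, adjusted over all genes or adjusted over the list alone (camera adjusted p = 0.999), with SOX9 at 0.13 ± 0.13 and PMP22 at -0.17 ± 0.17. None of 5 endothelial and fibroblast markers passed over all genes and 1, PDGFRB (0.50 ± 0.15), passed adjusted over the list alone (camera adjusted p = 0.346). PDGFRB passed over all genes without a count filter (edgeR adjusted p = 0.00844), with DESeq2 (0.0264), with limma-voom (0.0497) and with the length and GC trends removed (0.45, edgeR 0.0330). Its log2 fold change was 0.32 without WT library 1 and 0.70 without WT library 2. That of COL6A3 was 0.56 without WT library 2, beside 0.34 ± 0.16 with all libraries. Fits without a WT library take the spread from the M3 pair alone, so no p-value is given for them here. Haematopoietic and epithelial markers had 1 and 2 measured members and were not tested as lists, with CD68 at -0.76 ± 0.33, KRT19 at -0.76 ± 0.31 and MUC1 at -0.07 ± 0.54. None of these passed over all genes, and neither epithelial gene passed adjusted over the list alone. CD68 was the only measured member of its list, so its edgeR quasi-likelihood p of 0.0493 there is unadjusted. KRT19 was at -1.02 without WT library 2.

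In the list of IWS1 and TND or TIM partners, 4 of 17 genes rose and 2 fell (4 and 4 adjusted over the list alone, camera adjusted p = 0.587). The histone methyltransferases KMT2A (0.81 ± 0.22) and NSD3 (0.66 ± 0.19) and TFIIS itself (TCEA1, 0.66 ± 0.13) rose with IWS1, and the TFIIS paralogs TCEA2 (-0.63) and TCEA3 (-0.56) fell. Of 33 other elongation factors 5 rose and none fell (5 and 0 adjusted over the list alone; camera adjusted p = 0.999): the super elongation complex scaffolds AFF4 (0.99 ± 0.22) and AFF1 (0.93 ± 0.22), cyclin T2 (CCNT2, 0.76 ± 0.16), the PAF complex subunit CDC73 (0.76 ± 0.14) and the kinase CDK12 (0.68). Of 29 Mediator subunits 2 rose, MED13 (1.08 ± 0.21) and MED1 (0.57 ± 0.15), and 2 fell, MED8 (-0.55 ± 0.14) and MED24 (-0.50 ± 0.13), with 4 and 2 adjusted over the list alone (camera adjusted p = 0.587). Of 46 splicing factors SRSF10 rose (0.64 ± 0.12; 1 adjusted over the list alone; camera adjusted p = 0.999). Of the 12 genes named by the rule here besides IWS1, 9 lost the call without M3 library 1, 5 without M3 library 2 and 10 with the trends removed, where TCEA1 (0.45) and SRSF10 (0.69) stayed past the threshold. No elongation factor or Mediator subunit passed with the trends removed (0 higher and 0 lower in each list). AFF1 was at 0.50, AFF4 at 0.44, CCNT2 at 0.09 and CDC73 at 0.0002 there, and KMT2A was at 0.34 and NSD3 at 0.10. With total-count scaling 6 of the 12 lost the call. KMT2A (edgeR adjusted p = 0.0528) and NSD3 (0.0556) lost it with upper-quartile scaling and MED24 (0.0596) with the replicate block. KMT2A was at 0.48, NSD3 at 0.42 and AFF1 at 0.61 without WT library 1, and without WT library 2 KMT2A was at 1.24.

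Cell cycle lists had members on both sides. Of 47 G2/M genes 10 rose and 2 fell (11 and 2 adjusted over the list alone; camera adjusted p = 0.531). The mitotic genes GAS2L3 (2.15-fold), KIF20B (2.09-fold) and CENPE (1.94-fold) rose, and Aurora kinase B (AURKB, -0.76 ± 0.13) and UBE2C (-0.53) fell. With the length and GC trends removed GAS2L3 (log2 fold change 1.01) and AURKB (-0.37) stayed past the threshold, and KIF20B (0.24) and CENPE (0.12) did not. Of 46 S-phase genes 4 rose and 4 fell (4 and 4 adjusted over the list alone; camera adjusted p = 0.999), with the licensing factor CDT1 (-0.89 ± 0.14), TYMS (-0.57 ± 0.14), RFC2 (-0.55) and E2F1 (-0.53) lower and CCNE2 (0.80 ± 0.18), HELLS (0.68 ± 0.13), ATAD2 (0.55) and USP1 (0.44) higher. None of 24 replication-dependent histone genes passed, adjusted over all genes or adjusted over the list alone (camera adjusted p = 0.577), with the H2B gene HIST1H2BK at 0.13 ± 0.19 and the H1 gene HIST1H1C at -0.55 ± 0.25. HIST1H2BK passed with the trends removed (0.60, edgeR adjusted p = 0.0419) and HIST1H1C without a count filter (edgeR adjusted p = 0.0106). Without WT library 1 HIST1H2BK was at 0.42, and without WT library 2 HIST1H1C was at -0.90. Of 42 MYC and MYCN activated genes 3 rose and 4 fell (4 and 5 adjusted over the list alone; camera adjusted p = 0.159), with NME1 (-1.25 ± 0.18), HSPE1 (-0.97 ± 0.21), FBL (-0.75 ± 0.15) and SRM (-0.72) lower and UTP20 (0.72 ± 0.17), MDM2 (0.71 ± 0.14) and TFRC (0.57) higher. The MYC list passed without WT library 2 (camera adjusted p = 0.0299, and 0.876 with an estimated correlation).

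Of 36 genes of the WNT, Notch, BMP and Hedgehog pathways 5 rose and 8 fell (6 and 9 adjusted over the list alone; camera adjusted p = 0.587). WNT5A (1.42 ± 0.26), the receptors FZD3 (2.22-fold), FZD7 (0.88) and LRP6 (0.92 ± 0.21) and the Notch target HEY1 (0.57) rose. ID3, a BMP-induced helix-loop-helix inhibitor (-0.88 ± 0.14), ID1 (-0.82), ID2 (-0.64) and the pathway inhibitors SMAD6 (-0.71), SMAD7 (-0.57) and BAMBI (-0.80) fell. Of 24 immediate-early genes 2 rose, ETV4 (2.07-fold) and SPRY4 (0.61 ± 0.15), and JUND fell (-0.73 ± 0.14), with 2 and 1 adjusted over the list alone (camera adjusted p = 0.847). Of the 19 genes named by the rule from the cell cycle, MYC and signalling lists, 10 lost the call without M3 library 1, 6 without M3 library 2 and 10 with the trends removed, where the log2 fold change of FZD3 was 0.18 and that of ETV4 was 1.32. With total-count scaling TYMS lost it (adjusted p = 0.0740). HSPE1 was at -0.63 without WT library 1.

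Several stress genes were lower. Of 28 p53 targets 5 fell and 3 rose (9 and 4 adjusted over the list alone; camera adjusted p = 0.158). The growth factor GDF15 (-1.36 ± 0.25), the apoptosis genes BBC3 (-1.01 ± 0.18) and BAX (-0.85 ± 0.14), PHLDA3 (-0.70) and FDXR (-0.62) fell, and MDM2 (0.71 ± 0.14), RRM2B (0.66) and ZMAT3 (0.51) rose. Of 43 amino-acid and ER stress genes 6 fell and 2 rose (7 and 2 adjusted over the list alone; camera adjusted p = 0.0663), with CHAC1 (-1.36 ± 0.34), CEBPB (-0.83 ± 0.16), the regulator ATF4 (-0.81 ± 0.13) and DDIT4 (-0.76 ± 0.16) lower and SEL1L (0.74) and DNAJC3 (0.47) higher. With the trends removed both lists passed (camera adjusted p = 0.0156 for p53 targets and 0.0297 for stress genes) at medians of -0.19 and -0.10, and neither passed there with an estimated correlation (0.933 and 0.943). The stress list also passed with M3 library 2 left out (0.00961), without a count filter (0.0460) and with the replicate block (0.0377), and in none of these with an estimated correlation (0.863, 0.844 and 0.933).

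Other stress and metabolic lists gave no list call. Of 20 heat-shock and chaperone genes 3 rose and 2 fell (3 and 2 adjusted over the list alone; camera adjusted p = 0.999): DNAJB4 (0.90 ± 0.20), CHORDC1 (0.69 ± 0.13), HSPA4L (0.67 ± 0.18), HSPE1 and HSPB1 (-0.65). Of 39 hypoxia and glycolysis genes 3 rose and 3 fell (3 and 3 adjusted over the list alone; camera adjusted p = 0.999), with STC1 (1.57 ± 0.27), PLOD2 (0.49 ± 0.13) and ERO1A (0.45) higher and ALDOC (-0.76 ± 0.20), SLC2A1 (-0.47 ± 0.13) and ENO2 (-0.46) lower. Of 31 cholesterol synthesis genes 1 rose, STARD4 (0.58 ± 0.13), and 3 fell, TM7SF2 (-0.86 ± 0.19), FDPS (-0.64 ± 0.13) and FDFT1 (-0.45 ± 0.13), with 2 and 6 adjusted over the list alone (camera adjusted p = 0.706). Of 21 interferon-stimulated genes EIF2AK2 rose (0.99 ± 0.19) and IFI6 fell (-0.73 ± 0.17), with 1 and 1 adjusted over the list alone (camera adjusted p = 0.276, and 0.0275 without M3 library 2, where an estimated correlation gave 0.863). Of 12 NF-kB and cytokine genes BIRC3 rose (0.80 ± 0.22), with 2 higher and 3 lower adjusted over the list alone (camera adjusted p = 0.608). Of the 23 genes named by the rule from the stress and metabolic lists, 18 lost the call without M3 library 1, 11 without M3 library 2 and 13 with the trends removed, where STARD4 (-0.12) and HSPA4L (-0.05) changed sign. With total-count scaling 10 lost it, PLOD2, SLC2A1 and FDFT1 with the replicate block (adjusted p from 0.0710 to 0.0847), BIRC3 with DESeq2 (0.0632) and HSPA4L with upper-quartile scaling (0.0505). ALDOC was at -0.46, TM7SF2 at -0.57 and HSPA4L at 0.43 without WT library 1.

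Because IWS1 acts in elongation, fold changes were also compared by genomic span. The 1389 genes with the longest spans (168364 to 2473620 bp) were higher in M3, with a median log2 fold change of 0.36, 271 genes that rose and 12 that fell (camera adjusted p = 2.41e-13, and 0.249 with an estimated correlation). The 1389 genes with the shortest spans (53 to 4429 bp) were lower, with a median of -0.35, 16 that rose and 266 that fell (camera adjusted p = 3.68e-10, and 0.249 with an estimated correlation). Across genes, which are not independent replicates, Spearman's rho with the log2 fold change was 0.47 for span, 0.52 for transcript length and -0.54 for transcript GC content, and 0.18 for span at fixed transcript length and GC content. The WT libraries also differed from each other by transcript length, with a rho of 0.48 for WT library 2 minus WT library 1. With the length and GC trends removed the longest genes had a median of 0.09 and a call (camera adjusted p = 0.000108, and 0.298 with an estimated correlation), and the shortest a median of -0.09 and no call (0.129). Without WT library 1 the medians were 0.22 and -0.24, both with a call (camera adjusted p = 3.51e-10 and 2.06e-08, and 0.318 for each with an estimated correlation).

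**Figure D3:**
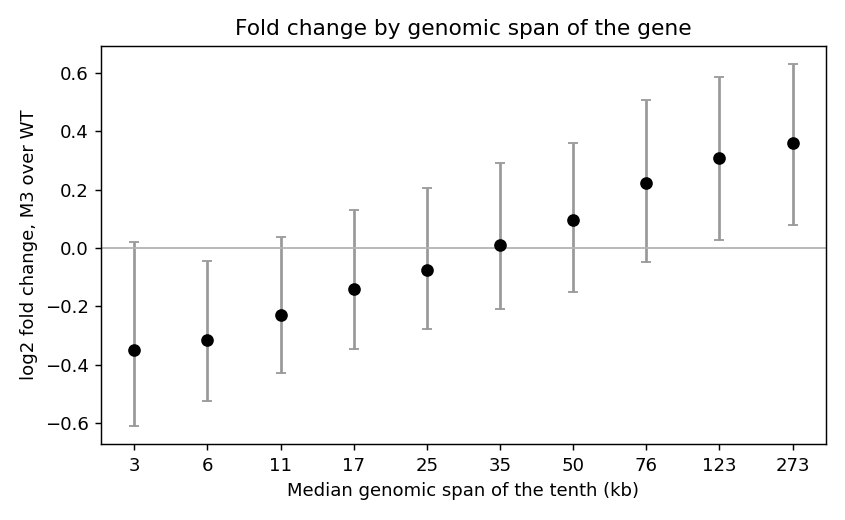
Median log2 fold change (M3 over WT, points) with the lower and upper quartile (bars) for 10 equal groups of the tested genes by genomic span, labelled by the median span in kb. The median runs from -0.35 in the shortest to 0.36 in the longest group.

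**Figure D4:**
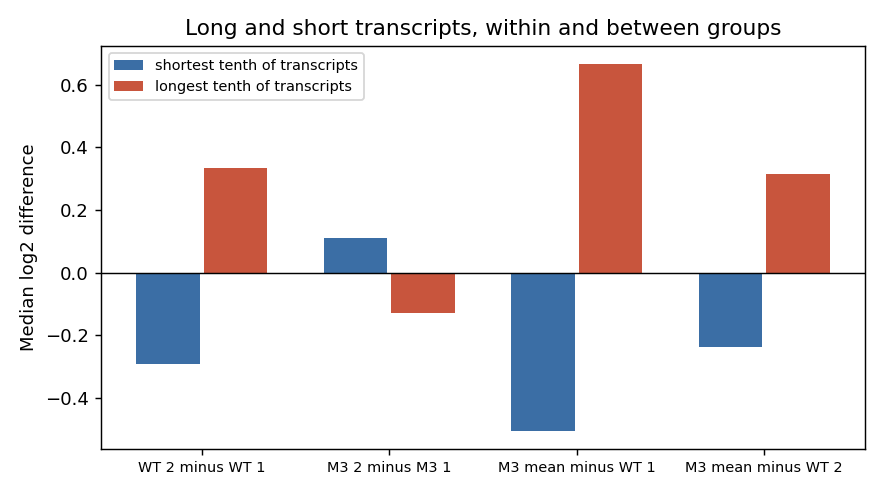
Median log2 difference between libraries for the 10% shortest and 10% longest transcripts, within WT, within M3, and for the M3 mean against each WT library. The bars for WT library 2 minus WT library 1 stand at -0.29 and 0.34, beside -0.24 and 0.31 for the M3 mean minus WT library 2.

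By chromosome, 8 of 23 had a shifted distribution of fold changes. Genes of chromosomes 13 (median 0.27), 18 (0.25), 4 (0.21) and 5 (0.14) were higher in M3, and genes of chromosomes 19 (-0.25), 22 (-0.18), 16 (-0.15) and 17 (-0.15) were lower, with camera adjusted p from 5.82e-06 for chromosome 19 to 0.0264 for chromosome 5. With an estimated correlation the adjusted p of each of the 8 was 0.409, and with the length and GC trends removed none of the 8 passed. Chromosome 5 lost the call without M3 library 1 (adjusted p = 0.0566) and without a count filter (0.0552), and chromosome 20 passed with the stricter filter (median -0.11, 0.0352, and 0.376 with an estimated correlation).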

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

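In this part the tests of length and GC bias, of genomic span and of matched lists were chosen after the result was seen. Reads assigned to no annotated feature, which enter no comparison of the report, took 26.6% of counted reads in M3 (SD 1.39, n = 2). In WT they took 23.2% (SD 0.00686, n = 2), and both M3 libraries lay above both WT libraries. The strand setting is not known, and with stranded counting such reads can also lie antisense to exons, which was not tested. Counts in 887 microRNA genes that lie inside introns were 35.3 and 42.2 CPM in WT and 64.1 and 60.2 in M3, a ratio of 1.61. These CPM were scaled to total gene counts, and the TMM factors, which are larger in M3, would lower the ratio. More unspliced or intronic RNA in the M3 libraries would give such a rise. For the 709 of these microRNA genes with a counted host gene, the exon counts of the hosts predict a ratio of 1.07. The observed ratio was 1.585, so the hosts do not account for it. Counts of the same 709 genes also differed within WT, at 1.18 times in WT library 2 over WT library 1. The share of reads assigned to no feature was nearly equal in those libraries. Genomic DNA stays open, because 537 genes of families these cells are not known to use had only 28 to 52 reads per library, too few to decide. They were at 2.35 and 2.34 CPM in WT and 2.28 and 3.83 in M3, a ratio of 1.32 with a 95% interval from 0.958 to 1.82 that covers counting error alone. The mutant stays open as a biological source of intronic reads, as do unrecorded differences between RNA preparations.

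Long AT-rich transcripts were higher and short ones lower in M3. A bias of transcript length and GC content between libraries may give part of this. WT library 2 minus WT library 1, within 1 group, followed transcript length with a rho of 0.476. For GC content the rho was weaker there, at -0.295, than for the M3 mean minus WT library 2, at -0.533. The M3 libraries also differed by transcript length (rho -0.295 for M3 library 2 minus M3 library 1). An effect tied to genomic span, as an elongation factor might give, cannot be told apart from such a length and GC bias. At fixed transcript length and GC content the rho of span was 0.179 for M3 minus WT and 0.124 for WT library 2 minus WT library 1. Ribosomal protein and snoRNA host genes had a median log2 difference of -0.751, below lists matched in part on length, GC content and abundance (median -0.385, central 95% from -0.448 to -0.330). The matched genes were longer (median 1108 against 886 nt) and less abundant (median 468 against 832 CPM) than the list. The list was also below its matched lists between the WT libraries (-0.464 against -0.343) and, by a wider margin, for the M3 mean minus WT library 2 (-0.531 against -0.200, central 95% from -0.272 to -0.158). As the WT libraries differ in the same way and the matching is incomplete, library bias and the mutant cannot be told apart for these genes either. The M3 mean minus WT library 2 still followed transcript length (rho 0.437), and an effect of the mutant on the whole trend stays open.

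The length and GC trends gave little of the higher count of IWS1, as far as its annotated transcript goes. The log2 fold change of IWS1 was 0.617 after they were removed (SE 0.0946, edgeR adjusted p = 0.00809), beside 0.646 before. That transcript (2958 nt, 47.5% GC) lies near the medians of tested genes (3052 nt, 49.4%), so the correction could change the value little. The length and GC content of the vector transcript were not used, so a bias on its reads was not tested. As a hypothesis, vector dose or the stability of the mutant transcript may differ between the transduced pools, and reads from the vector were not separated here.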

How the results depend on the processing

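No gene called in the reported fit was called in the opposite direction under any other setting, and counts of changed genes stayed within 1.5 times under median-of-ratios or upper-quartile scaling, the stricter filter, DESeq2, limma-voom and the fit on annotated genes (2065 to 2529). The cause was not tested for the changes below unless named. Without a count filter 3945 genes changed (2065 higher, 1880 lower) among 20290 tested. Leaving out 1 library, so that the spread comes from the other pair and the lone library is assumed to vary alike, gave 366 to 6770 changed genes (286 to 3441 higher, 80 to 3329 lower), lowest without M3 library 1 and highest without WT library 2. IWS1 ranged from 0.60 to 0.69 over these fits and lost the call without M3 library 1 or 2. Of 112 called genes taken by the naming rule besides IWS1, 66 lost the call without M3 library 1, 32 without M3 library 2, 3 without WT library 1 and 2 without WT library 2, and 4 lost it with upper-quartile scaling, 4 with DESeq2 and 3 with limma-voom. A 2-fold threshold left 353 genes, and an adjusted p of 0.01 left 0 with edgeR and 0 with limma-voom but 1258 with DESeq2, where 5078 had an unadjusted edgeR p below 0.05.

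Settings chosen after seeing the data follow. Total-count scaling gave 1120 genes (856 higher, 264 lower), and 29 named genes lost the call. The correction for GC content and transcript length gave 661 (286 higher, 375 lower), and with the replicate block 813 (350 higher, 463 lower). Under the correction alone 54 named genes lost the call and HIST1H2BK and PDGFRB gained one. Among those lost, STARD4 went to -0.116 (-0.116 with the block) and HSPA4L to -0.0496 (-0.0430 with the block).

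The replicate numbers share no stated batch, and the deviations of same-numbered libraries correlated at -0.144 over 14141 genes. With the number as a block 2315 genes changed, 5 named genes lost the call and the amino-acid and ER stress list passed (camera adjusted p = 0.0377). Crossed pairing gave 5314 genes (2794 higher, 2520 lower).

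Of 30 lists, 4 to 9 passed with 1 library left out (lowest without WT library 1, highest without M3 library 2) and 6 with the correction. Without a count filter the channel and matrix lists lost the call and the HOX and stress lists gained one, and with the stricter filter the channel list lost it. No set that passed under any of these settings passed there with an estimated correlation. That test has few degrees of freedom with so few libraries, so this does not show that correlation between genes explains the calls. In the reported fit 0 passed with an estimated correlation (0 with an unadjusted p below 0.05), and with fry 0 (6 unadjusted). With the correction the neuronal differentiation and axon list (median 0.04) passed with fry (adjusted p = 0.0404). It did not pass there with camera (adjusted p = 0.371, and 0.943 with an estimated correlation). The genes of longest span had a median of 0.36 and those of shortest span -0.35 with adjusted p = 0.249 with an estimated correlation. The shortest had -0.151 without a filter (adjusted p = 0.223), -0.0941 with the correction and -0.0894 with the correction and block (0.148). Of the chromosomes 0 passed with the correction (1 with an unadjusted p below 0.05, 0 with fry), 0 with the correction and block, and 0 with an estimated correlation (1 unadjusted, 2 with fry). The simulated test found 19.4% of genes changed 1.5-fold. It made 128 calls, so its p cutoff was stricter than that of the reported fit with 2232 calls, and this share does not carry over. The reported fit called some smaller changes, such as MED24 (1.42-fold lower in M3), but can still miss others.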

Other observations

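Genes outside the rule for named genes were looked up after their values were seen. LIN28B, which blocks let-7 microRNA maturation and is often active in neuroblastoma, was higher in M3 by a log2 fold change of 1.02 ± 0.14 (SE; 92.7 and 116 CPM in WT, 219 and 204 in M3), and by 0.49 ± 0.09 with the length and GC trends removed (edgeR adjusted p = 0.0144). LPCAT1, an enzyme of phospholipid remodelling, was higher by 1.34 before and 1.41 ± 0.16 after the correction (adjusted p = 0.00245), and the growth factor TGFB3 by 0.88 before and 1.01 ± 0.15 after (adjusted p = 0.00743). The nuclear noncoding RNA NEAT1 was at 248 and 335 CPM in WT and 216 and 222 in M3, with a log2 fold change of -0.42 ± 0.15 that did not pass (adjusted p = 0.0909) and of -1.04 ± 0.10 after the correction (adjusted p = 0.00163).

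RN7SL1 and RN7SL2, the RNA of the signal recognition particle, were higher in M3 (log2 fold change 0.85 ± 0.17 and 1.18 ± 0.21, edgeR adjusted p = 0.0244 and 0.0204), at 288 and 291 against 430 and 617 CPM for RN7SL1, though short GC-rich transcripts were mostly lower. They have many near-identical copies in the genome, and the libraries were made from poly(A) RNA, so their counts are uncertain. RMRP had 33 and 268 reads in WT and 38 and 51 in M3, and RPPH1 35 and 188 in WT and 29 and 30 in M3, so that both had most reads in WT library 2, and neither passed (edgeR adjusted p = 0.190 and 0.0719). The mitochondrial 16S rRNA RNR2 was at 33440 and 25615 CPM in WT and 20181 and 19971 in M3 (log2 fold change -0.56 ± 0.26, adjusted p = 0.160).

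A hypothesis fixed before its result was seen was that M3 libraries may hold more RNA from past gene ends. Among weakly counted genes, the 156 within 10 kb downstream of a well counted gene had a median log2 fold change of 0.07 and the 1291 without such a neighbour one of 0.12, a difference of -0.0487 (permutation p = 0.291; bootstrap 95% interval -0.111 to 0.0678). Both medians were scaled to total gene counts, so they are not relative to the TMM centre. With that scaling the median log2 fold change of all tested genes was 0.11. The median count was 8 per library, too few to decide.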
